A study of Rattus norvegicus with 8 samples.

How the data were processed

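Total RNA from whole lungs of rats 14 days old was measured on 8 single-colour Illumina RatRef-12 bead arrays, 1 array per lung. The lungs fell into 2 groups of 4: controls, and lungs of animals exposed to maternal diabetes, which had been induced in the female before pregnancy with streptozotocin (35 mg/kg), a toxin of the insulin-producing pancreatic beta cells. Hybridised material was detected with Cy3-streptavidin, per the labels' protocols.

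The deposited raw table holds, per the file headers, mean bead intensities for 22226 probes from BeadStudio version 1.5.0.34 with normalization set to none. All raw intensities were positive, and the headers name no background step. Beside each intensity the authors deposited a detection score, a fraction between 0 and 1 that rose with the signal and was read as 1 minus the detection p. Its steps correspond to ranks among about 825 negative control probes. The number of beads behind each value is another deposited quantity of the raw table, used here only to describe the arrays. Another 8 columns of the raw table, the spread of the beads on each array, were not used here. The deposited value table holds intensities on a linear scale that are normalized between arrays by the authors. Set against a quantile normalization of the raw table, 97.7% of its values lay within 0.1 units and nearly all within 1 percent, and its column medians ran from 93.7 to 93.8. The submitters' processing notes name limma, with no version.

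Each column of the raw table carries its sample's identity in the line above the header. The columns' own names hold 2 codes, 1 on all control arrays and the other on all exposed arrays. Each name also holds a letter shared by its group and a number of its own. Within each group these numbers run in sequence. What the codes and numbers stand for is not given in the sources used here, so 1 litter per group remains possible. Neither table pairs a probe with a gene, and 0 of the probe identifiers occur in the reference gene table that was at hand. The 22 cell type marker lists and 31 other gene lists fixed beforehand, and the rule for genes to be named, could therefore not be applied, and no gene list was tested. In their place the 2 probes with the largest rise and the 2 with the largest fall were named, among probes past the threshold whose groups did not overlap. This shortens the first part of the rule fixed beforehand, which ranks called probes by the size of the rise and of the fall.

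Raw intensities were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3: normexp with negative controls inferred from the detection p, an added offset of 16, quantile normalization and log2. The offset shrinks the differences of dim probes. Probes with a detection p under 0.01 on at least 4 of the 8 arrays were kept, which left 9900. A linear model with 2 groups was fitted per probe over all 8 arrays with no covariate. The moderated statistics of limma were used two-sided, with Benjamini-Hochberg adjustment over the 9900 probes and a threshold of 0.05. The difference is exposed minus control, in log2 units, and its error is the model's standard error (SE). Measures with 1 value per array were compared with exact two-sided permutation tests over the 70 assignments of arrays to groups, whose smallest possible p is 0.0286.

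The procedure was tested on simulated data made from the means and residual variances of the same 9900 probes, with a random set of probes changed in the comparison of exposed with control lungs. It recovered 50.0% of 68 probes changed by 0.3 log2 units, 81.8% of 66 changed by 0.5 and 89.4% of 66 changed by 1. Of 159 calls 12 were false, and a simulation with no changed probe gave 0 calls. The simulated noise was independent between probes and only a small share of the probes was changed. In the real arrays many probes vary together, so these rates may not hold for them. On arrays the number of animals limits the precision: the median SE of a difference was 0.060 log2 units, and the median 95% interval reached 0.14 log2 units to either side. The median number of beads per probe was 42 or 43 on each array.

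No label says whether the lungs of a group came from 1 litter or several, nor names a chip, a position or a scan batch for an array. The p-values measure the spread between these lungs, and they carry no information on spread between dams if a group came from 1 dam. The replicate numbers 1 to 4 occur in both groups. The labels do not say that a number joins 2 lungs, and the deviations of same-numbered arrays from their group means did not all correlate, so the model has no replicate block. No 2 arrays held identical values; at most 0.49% of probes had equal raw signals in any 2 arrays.

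Alternatives fixed before the data were examined were other background corrections and normalizations, the deposited value table, other filters on dim probes, array weights, other variance priors, the replicate number as a block, other thresholds, and leaving out each array in turn. Alternatives chosen after seeing the data left out 2 arrays that shared a set of raised probes, 2 control arrays low in 3 bright probes, or the probes that stood apart on 1 array.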

Results

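The lungs of 4 control rats and of 4 rats exposed to maternal diabetes were profiled at 14 days of age, when the rat lung is still forming alveoli. The series addressed which lung transcripts differ after exposure to maternal diabetes. Between 9508 and 10188 of the 22226 probes were detected per array at a detection p under 0.01. The controls had 9773 ± 177 detected probes (SD, n = 4) and the exposed lungs 9866 ± 277 (SD, n = 4), a difference that the exact permutation test did not separate from the spread between arrays (two-sided p = 0.57). The median log2 raw signal was 6.57 ± 0.06 in controls and 6.53 ± 0.03 in exposed lungs (SD, n = 4 each; exact permutation p = 0.26). Over the 9900 probes tested, arrays correlated at a mean of 0.993 within controls, 0.991 within exposed lungs and 0.989 between the groups. These correlations are across probes, which are not independent replicates.

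The differences called after exposure to maternal diabetes were mostly small. In the comparison of exposed with control lungs, 119 of the 9900 probes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg). Of these, 36 were higher and 83 lower in the exposed lungs. The median size of a called difference was 0.38 log2 units, or 1.30-fold, and the sizes ran from 0.16 to 1.51 log2 units. Only 19 called probes differed by at least 1.5-fold, 6 of them higher and 13 lower, and 3 by at least 2-fold, 2 higher and 1 lower. All 119 called probes had groups that did not overlap. Among all tested probes 1126, or 11.4%, had such groups, where chance gives 2.86% on average over the splits of the arrays. The other 34 splits gave 47 to 1031 such probes, counted after the result was seen.

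The number of called probes rested on nearly every array. Leaving out exposed replicate 1 gave 124 calls, and leaving out control replicate 3 gave 31. It fell to 17 without control replicate 4, 8 without control replicate 1, 4 without control replicate 2, 9 without exposed replicate 3, 1 without exposed replicate 4 and 0 without exposed replicate 2. In that last fit 1554 probes had an unadjusted p under 0.05 by limma.

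**Figure D1:**
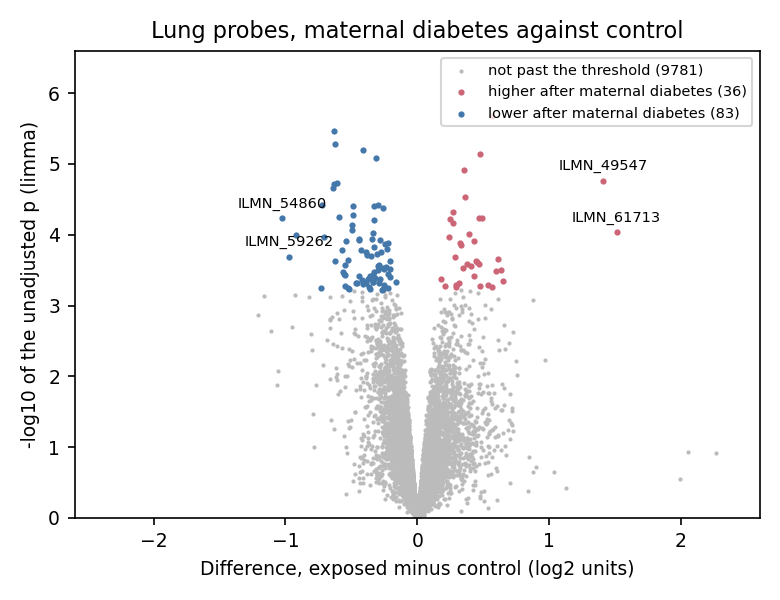
Each point is a probe, with the difference between exposed and control lungs in log2 units on the x axis and the -log10 of the unadjusted limma p on the y axis. The 36 probes higher and 83 lower after maternal diabetes are coloured, and the 3 points farthest to the right lie low on the y axis and were not called.

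The deposited tables do not pair probes with genes, so the named probes are given by their array identifiers. ILMN_61713 showed the largest rise among called probes with the normalization used here. Its normalized log2 signal was 11.15 ± 0.41 in controls and 12.66 ± 0.24 in exposed lungs (SD, n = 4 each), a difference of 1.51 ± 0.21 (SE) or 2.86-fold (limma, adjusted p = 0.031). ILMN_49547 went from 7.06 ± 0.16 to 8.48 ± 0.31 (SD, n = 4 each), a difference of 1.41 ± 0.15 (SE; limma, adjusted p = 0.019). This probe was close to background in controls, where 3 of the 4 arrays detected it, and detected in all 4 exposed lungs. Without background correction ILMN_49547 rose by more than ILMN_61713, by 1.92 against 1.46 log2 units, as it did in the deposited value table (1.92 against 1.46) and with normexp without control probes (1.96 against 1.46). The raw intensity of ILMN_49547 was 132 ± 38.8 in controls and 458 ± 104 in exposed lungs (SD, n = 4 each).

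With the same normalization, the largest fall among called probes was that of ILMN_54860, whose log2 signal was 10.03 ± 0.16 in controls and 9.01 ± 0.25 in exposed lungs (SD, n = 4 each). The difference was -1.03 ± 0.13 (SE), so that the control level was 2.04-fold that of the exposed lungs (limma, adjusted p = 0.024). ILMN_59262 had 9.06 ± 0.29 in controls and 8.09 ± 0.18 in exposed lungs (SD, n = 4 each), a difference of -0.97 ± 0.15 (SE; limma, adjusted p = 0.037). Both were detected on all 8 arrays. With single arrays left out, each of the 4 named probes lost its call without any 1 of control replicates 1, 2 and 4 and exposed replicates 2, 3 and 4. The adjusted p in these fits ran from 0.053 to 0.083 for ILMN_61713, from 0.053 to 0.071 for ILMN_49547 and from 0.057 to 0.083 for ILMN_54860. For ILMN_59262 it ran from 0.056 to 0.119 (limma, adjusted p), control replicate 3 included. The differences in the same fits ran from 1.37 to 1.56 log2 units for ILMN_61713, 1.36 to 1.53 for ILMN_49547, -1.04 to -0.92 for ILMN_54860 and -1.05 to -0.84 for ILMN_59262.

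**Figure D2:**
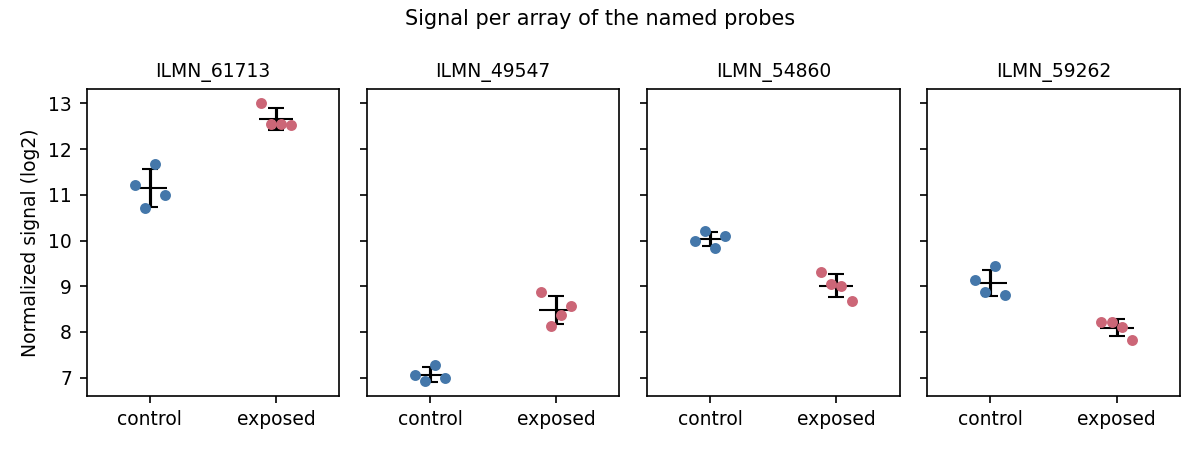
Normalized log2 signal (y axis) of the 4 named probes in each of the 4 control and 4 exposed lungs; points are arrays, and the bars are the mean and SD of a group. In every panel the 4 exposed lungs lie wholly above or wholly below the 4 controls, and exposed replicate 1, at 13.01, stands above the other exposed lungs for ILMN_61713.

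An unadjusted p under 0.05 was reached by 1716 probes, 697 higher and 1019 lower, where 495 are expected with no change and 1 split of the arrays that mixed the groups gave 1773. The share of probes estimated to be unchanged was 60.9% by limma's convex decreasing density estimate and 72.1% by its local false discovery rate estimate. Since a split that mixed the groups gave as large an excess of low p-values, these shares do not measure a response to maternal diabetes. The excess of lower over higher probes depended on the scaling: 40.6% of the 1716 were higher with quantile normalization, against 5.35% of 897 when arrays were centred on their medians, a setting that called 0 probes. That setting moved the median difference from -0.01 to -0.06 log2 units. Its medians were taken over all 22226 probes, most of them not detected at a detection p under 0.01. It therefore scaled the arrays by dim probes.

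The precision of the differences is known for the 9900 probes that passed the detection filter, and not for the dimmer probes among the 22226. For 9168 of the 9900, or 92.6%, the 95% interval of the difference lay wholly within 1.5-fold in either direction, and for 7 it lay wholly beyond 1.5-fold. These intervals are on values whose added offset shrinks the differences of dim probes. With the tested probes ranked by mean level into 3 classes of equal size, 7 called probes came from the dimmest class, 59 from the middle and 53 from the brightest. The SD of the fitted differences over all probes was 0.165 log2 units.

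The largest fitted differences were not called. The largest, 2.27 ± 1.31 log2 units (SE; limma, adjusted p = 0.41), came from a probe whose controls spread with an SD of 3.02 while the exposed lungs spread with an SD of 0.16. In a principal component analysis of the 9900 probes the first component held 38.5% and the second 29.8% of the variance. Groups overlapped on the first component (two-sided exact permutation p = 0.057) and on the second (p = 0.31 by the same exact test), where exposed replicate 1 lay at -19.8 and the other 7 arrays between -3.75 and 9.35. In exposed replicate 1, 45 probes lay more than 1 log2 unit above each other exposed lung, and 0 of these were among the 119 called probes.

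**Figure D3:**
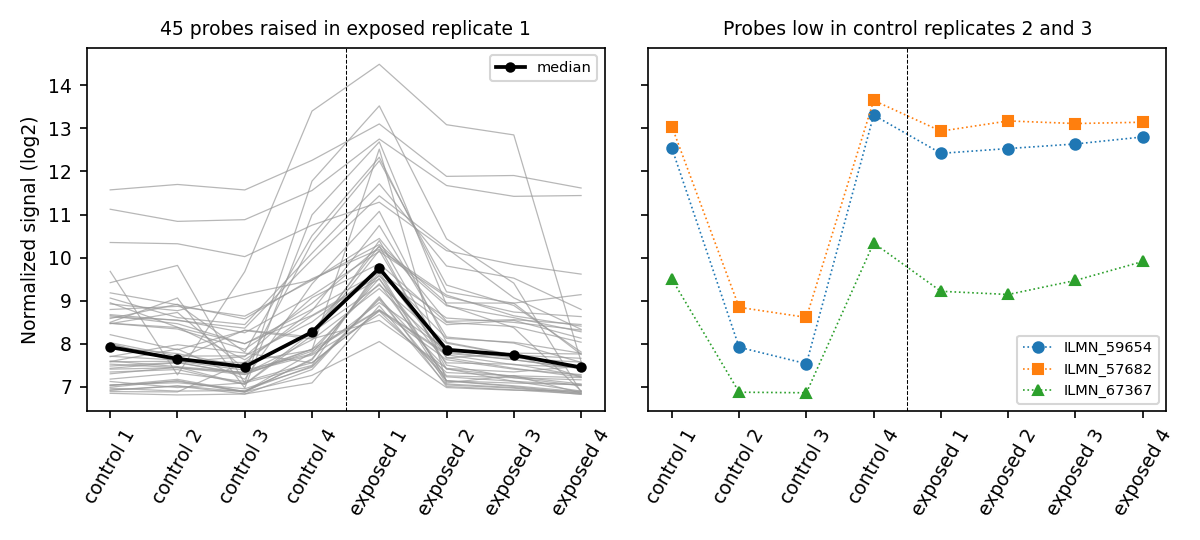
Normalized log2 signal (y axis) on each of the 8 arrays (x axis) for the 45 probes raised in exposed replicate 1 (left, 1 line per probe, median in black) and for 3 probes low in control replicates 2 and 3 (right); lines join values of 1 probe and imply no order of the arrays. On the left the median peaks in exposed replicate 1 at 9.76 and is next highest in control replicate 4 at 8.27.

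**Figure D4:**
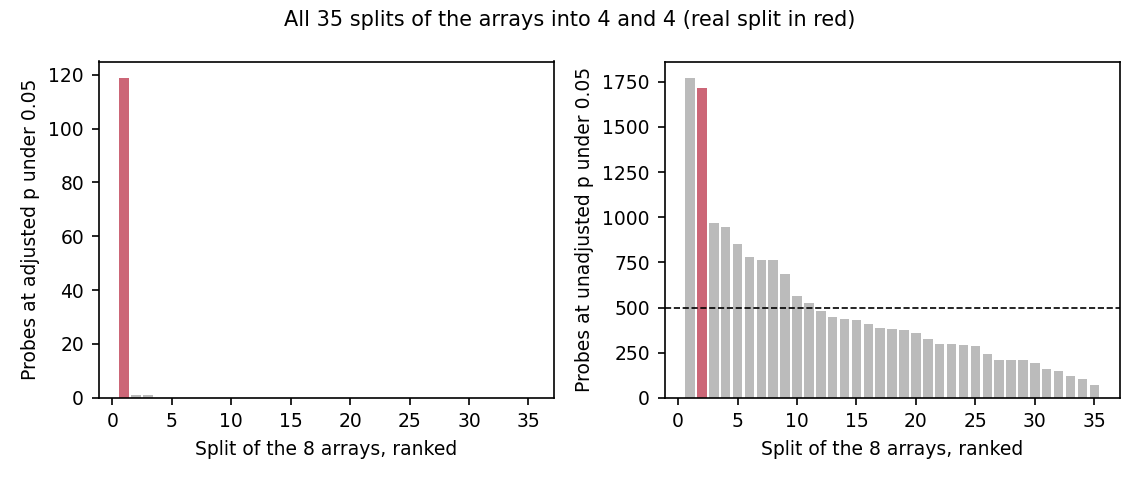
Number of probes past an adjusted p of 0.05 (left y axis) and past an unadjusted p of 0.05 (right y axis) for each of the 35 ways to split the 8 arrays into 4 and 4, ranked on the x axes, with the real split in red. The dashed line marks the 495 probes expected with no change; the real split gave 119 and 1716 probes, and 1 other split gave 1773 at the unadjusted threshold.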

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

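All tests in this part were chosen after the result was seen. Of 24 sets of 4 values examined, 6 held a value far from the other 3. Chance gives about 1 such set in 20 for independent sets of normally distributed values. Most of the 6 sets were small counts of probes, for which that rate does not hold, and the sets were not independent. Control replicate 2 had 9508 detected probes, against 9850 to 9883 in the other controls. For ILMN_61713 exposed replicate 1 stood at 13.01, against 12.53 to 12.55 in the other exposed lungs. Counting probes more than 1 log2 unit below the other 3 arrays of the group, exposed replicate 4 had 18, against at most 1 in the other exposed lungs, and control replicate 3 had 3, against 1 in each other control. Counting probes more than 1 log2 unit above, exposed replicate 1 had 45, against at most 2 in the other exposed lungs, and control replicate 4 had 10, against at most 1 in the other controls.

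The 45 probes raised in exposed replicate 1 rose there by a median of 1.93 log2 units over the other exposed lungs, 20 of them by more than 2, and 0 of them were called between the groups. Whether maternal diabetes raised these probes in every exposed lung stays open. Exposed replicates 2 to 4 lay 0.085 log2 units (median, with quartiles -0.06 and 0.20) above control replicates 1 to 3. This lay between the bounds of 0 and 0.3 set for that test. The probes were picked for low values in exposed replicates 2 to 4 relative to replicate 1, which tends to lower this difference. Control replicate 4, which was high in these probes, was left out of the controls compared, which tends to raise it. These choices act in opposite directions, so the value cannot decide the question. A fault of 1 array is argued against for most of these probes. Control replicate 4 carried them at a median of 0.61 log2 units over the other controls, with 95.6% of them above the other controls' mean. This array was picked for having the largest such excess apart from exposed replicate 1. A single mixed-in tissue or cell source present in different amounts may account for most of the set and stays open too. With normalized signals on a linear scale, the excess in control replicate 4 was a median 0.21 of that in exposed replicate 1. Of the probes, 77.8% lay within a factor of 2 of that ratio, short of the 80% set for it. Those outside it included ILMN_52784 at 0.016 and ILMN_54837 at -0.15.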

How the results depend on the processing

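All 119 called probes kept their direction under the other background corrections and normalizations and in the deposited value table. None of the alternatives is a test of direction, since these probes were called on the same arrays and their groups do not overlap. Of the 119 calls, 80 stayed without background correction and 80 in the deposited value table, nearly the same normalization. Cyclic loess kept 89, normexp without control probes 79 and the trend and robust prior 83. The filter to probes detected on all arrays kept 113, and dropping probes that stand apart on 1 array kept 119. In these fits the count stayed within 1.5 times of the 119, 36 higher and 83 lower. Median centring called 0 probes (897 at an unadjusted p under 0.05 by limma). With no filter on dim probes 43 were called, 13 higher and 30 lower, with a fold spread of 0.111 over 22226 probes. Array weights gave 275 calls, 100 higher and 175 lower. No moderation of the variances gave 14, 5 higher and 9 lower. A threshold of 0.10 gave 353 calls, and a fold of at least 1.5 left 19. Leaving out each array in turn gave 0 to 124 calls, 0 to 50 higher and 0 to 74 lower, of which 0 to 69 were among the 119; the fold spread ran from 0.147 to 0.188, and the difference in detected probes from -15 to 197.3, the negative value being that without exposed replicate 1. Chosen after seeing the data, leaving out control replicate 4 and exposed replicate 1 gave 22 calls (9 higher, 13 lower) and a fold spread of 0.194, and leaving out control replicates 2 and 3 gave 5 (1 higher, 4 lower). With the replicate number as a block, 0 probes were called by limma and 1963 had an unadjusted p under 0.05. Deviations of same-numbered arrays correlated at 0.11, 0.30, 0.07 and -0.06, and only number 2 correlated best with its own number, so the numbers were not taken as pairs. For the 4 named probes, 40 of 87 alternative fits kept the call, 47 lost it, with adjusted p from 0.0072 to 0.22. The differences ran from 1.34 to 1.69 log2 units for ILMN_61713, 1.26 to 1.96 for ILMN_49547, -1.16 to -0.88 for ILMN_54860 and -1.10 to -0.82 for ILMN_59262. With a detection p under 0.05, and with the 75th percentile in place of the median, the array measures again did not separate the groups (exact permutation p = 0.20 and 0.51). The cause was not tested for any of these changes, except that fits without an array have fewer samples. The tests of gene lists and their alternatives were not run, for want of gene names, nor was a block by slide, as no slide is named. Signal near background limits the dim probes, and those under the detection filter were tested only in the fit without it.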

Other observations

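The test of array brightness was fixed before its result was seen; the other tests in this part were chosen after. Of the 22226 probes, 51 had a gap of more than 1 log2 unit that parted the 8 arrays into a low and a high side. No gap of that size parted the exposed lungs from the controls (0 probes). Counting each probe by its largest gap only, 42 of them parted a single array, 31 being high in exposed replicate 1 and 8 low in exposed replicate 4.

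Chance as the source of the 119 calls was tested over the 35 splits of the arrays into 4 and 4. No other split called as many, the highest other count being 1, so 1 split, the real one, reached it, and the same held for the higher and for the lower probes. The real split thus ranked first for these counts, at 1 in 35, the smallest share these splits can give. That share is too coarse to exclude chance, and the counts were chosen after the result was seen. The higher and the lower probes are parts of the same 119 and add no separate evidence. Chance cannot be excluded for the broader measures either. For probes at an unadjusted p under 0.05 and for the spread of the differences, 2 splits were as large. These were the real one (1716 probes, 0.165 log2 units) and that of control replicates 1, 2 and 4 with exposed replicate 1 against the rest (1773 probes, 0.166 log2 units). The test of array brightness could not decide. Adding each array's median raw signal to the fit left the called probes' differences at a median of 1.00 times their size. The median SE was 0.061 against 0.059 without it. In that fit, which has 1 residual degree of freedom fewer, 10 probes were called by limma, and all 119 kept their direction. The called probes were selected for differences well above the spread within groups, and brightness overlapped between the groups. A covariate of that kind could change their differences little, whatever the role of brightness. A litter or other unit shared by a whole group cannot be told apart from maternal diabetes if the 2 codes in the column names mark such a unit, because 0 of them occur in both groups.

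The fitted difference was largest for 2 probes that were low in control replicates 2 and 3 and high in the other 6 lungs, and 1 more probe parted the arrays in this way. ILMN_59654 averaged 7.73 in the 2 low lungs and 12.70 in the 6 others, ILMN_57682 8.73 and 13.17, and ILMN_67367 6.87 (background, detected in 0 of the 2 low lungs) and 9.60, all in log2 units and picked after their values were seen. Only 0.018% of all probes, these 3 included, parted these 2 arrays from the rest by more than 1 log2 unit. That argues against a fault that shifted many probes of these 2 arrays by that much. It cannot decide on a smaller fault, since gaps of that size were rare along any line, at 0.229% of all probes. A fault limited to a few probes was not tested. The sex of the animals, which the labels do not give, is a candidate explanation that could not be tested without gene names. One probe, ILMN_61760, parted the same lungs the opposite way by a gap of 1.02 log2 units. However, ILMN_59654 and ILMN_57682 were detected in the 2 low lungs. Gaps of more than 1 log2 unit also parted the arrays along other lines: ILMN_60565 was low in control replicate 1 and exposed replicates 1 and 3. Sex of the animals could not be separated from an inherited difference between animals, which was not tested. The exposed lungs all lie on the high side of the division made by ILMN_59654, ILMN_57682 and ILMN_67367.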
